A study of Mus musculus with 2 samples.

How the data were processed

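The series holds H3K9ac chromatin immunoprecipitation sequencing (ChIP-seq) of mouse hindbrain at embryonic day 15.5 from strain B6NCrl. Per the labels, embryos were healthy and males and females were pooled. There was 1 group of 2 biological replicates, with 78 embryos in replicate 1 and 62 in replicate 2, and the size range of both libraries was 300 to 500. No other tissue, stage or treatment belongs to the series.

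Per the deposited text files, reads had been aligned to mm10 and filtered by the authors before peaks were called. The list of each replicate was derived from that replicate's filtered alignments and 1 control file. The pooled list was derived from the alignments of both replicates and both control files. The list of replicated peaks was derived from these lists, by a rule that is not given in the sources used here. The aligner, the peak caller, their versions and their thresholds are not given in the sources used here. The deposited enrichment of each peak is a ratio of signal over background as the authors' peak caller gave it, and its exact denominator is not stated. The deposited −log10 p and −log10 q values of each peak also came from the authors' peak caller. Every deposited −log10 p-value was at least 2.0 in replicate 1 and 2.02 in replicate 2. The lowest −log10 q was 0.22 in replicate 1 and 0.18 in replicate 2, and 74.8% and 78.0% of their peaks had a −log10 q of at least 2. Reads and alignments were not analysed here, so the read depth of both libraries is unknown. Binomial intervals therefore cover the counting of peaks and genes only, and the enrichment of the replicates was compared only by correlation, without a test of a difference between them.

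All positions are mm10 positions, counted from 1. Transcript starts came from GENCODE mouse release M21, with 55413 annotated genes, of which 21938 protein-coding genes lay on the 21 main chromosomes. RefSeq annotation release 108 gave additional gene starts and tRNA genes. A start-site peak of a gene was a peak that touched the region within 1000 bases of any of its annotated transcript starts, and a gene was called occupied when the lists of both replicates had such a peak. A peak was called shared when at least 1 base of it was covered by a peak of the other replicate. A distal peak lay over 5000 bases from every annotated transcript start. The domain of a gene was made from pooled peaks separated by gaps of up to 1000 bases, and its length is the number of bases covered by peaks. A promoter was called CpG-rich when its observed over expected CpG ratio within 500 bases of the gene's 5′ end was at least 0.6. Chance levels came from 100 shuffles of a list within chromosomes, outside assembly gaps.

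The choices of this paragraph were made before the data were examined. Fisher's exact test, two-sided, compared shared with single-replicate peaks, Hox paralog groups 1 to 5 with groups 6 to 13, hindbrain with forebrain transcription factors, the X chromosome with autosomes, and CpG-rich with CpG-poor promoters. The same test compared each of 28 fixed gene lists with all other protein-coding genes. The lists cover general neuron, neural progenitor, cell cycle, granule lineage, Purkinje and other GABAergic cerebellar, hindbrain transcription factor, serotonergic, motor and cholinergic, neurotransmitter, mid-hindbrain boundary, forebrain transcription factor, Hox 1 to 5, Hox 6 to 13, oligodendrocyte, astrocyte, microglia, endothelial, pericyte and meningeal, choroid plexus, red blood cell, liver, muscle and heart, sensory ganglion, germ cell, housekeeping, histone acetylation and immediate early genes, and developmental transcription factors of other organs. They hold 445 entries of 428 genes, of which 427 had an annotated start, and 16 genes were in more than 1 list. Two-sided permutation tests with 100000 random gene lists of the same size compared the mean rank of a list's peak enrichment (strength) and domain length (breadth) in the pooled list; a gene without a peak ranked lowest. Benjamini-Hochberg adjustment covered the 28 lists within each test, and a list was called at an adjusted p under 0.05. The smallest p these permutations can give is 1e-05. Genes are not replicates, so these tests place a list among other genes in these libraries. No test was made between the replicates.

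The names in the text follow a rule fixed before the data were examined. They are the 2 members of each list with the strongest start-site peak among occupied genes, the first 2 members in alphabetical order without a peak in either replicate, the 5 strongest and 5 widest genes, the 5 strongest distal peaks, the 3 strongest peaks of each replicate without a counterpart, any Hox gene, and every member of a list with 5 or fewer members on the minority side of a call. Names beyond this rule are said to have been chosen after their values were seen.

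Alternatives covered peaks with a −log10 q of at least 2, an enrichment of at least 3 or the upper 50% of a list by enrichment. Start windows of 500 and 2000 bases, the gene's 5′ end alone, the replicated and pooled lists and each replicate alone were also tried. Further alternatives were overlaps of at least 50% of a peak or of both peaks, equal numbers of top peaks, −log10 p in place of enrichment, merging gaps of 0 and 3000 bases, genes with a peak only, a CpG split at 0.75, a background matched over 10 classes of promoter CpG content, and distal limits of 1000 and 10000 bases. Alternatives added after seeing the data were stricter peaks of 1 replicate against the full list of the other, chromosomes without olfactory and vomeronasal receptor genes, starts extended by RefSeq gene starts and tRNA genes, and breadth with 1 gene kept per domain. A set of 36 gene families, taken by symbol, was also defined after seeing the data.

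The list tests were tested on simulated data with the 21938 real genes. Among 200 random lists of 15 genes without a planted effect, Fisher's exact test called 1.5% and the rank permutation test 2.0%. With a planted share of occupied genes of 0.95 they called 83.5% and 47.0%, with 0.8 they called 17.0% and 16.0%, with 0.3 they called 73.5% and 72.5%, and with 0.1 they called 100.0% and 99.0%. Here a simulated list counted as called at a raw p under 0.05, with fewer random lists than in the real tests. No adjustment over lists was made, so these rates are not those of the adjusted calls. Each gene's occupancy was drawn on its own, so genes that share a peak were not simulated. Near-identical promoter copies were sought among the main chromosomes only, as alignments of at least 95% identity over at least 50% of the promoter. The tools were Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, matplotlib 3.10.9, bedtools 2.31.1 and minimap2 2.31. Peaks on unplaced scaffolds were left out of all comparisons except the overlaps between lists. No signal outside peaks was measured.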

Results

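H3K9ac, an acetylated histone mark found at active promoters and some enhancers, was mapped by ChIP-seq in mouse hindbrain at embryonic day 15.5. At this stage the hindbrain holds the growing cerebellum, the pons and the medulla. The 2 biological replicates were pools of 78 and 62 embryos of both sexes. Replicate 1 had 46956 peaks over 31.32 Mb and replicate 2 had 42375 peaks over 29.26 Mb, while the pooled list of the series had 50422 peaks over 36.92 Mb. Read depth is unknown. In what follows, a gene is called occupied when both replicates have a peak within 1000 bases of one of its annotated starts. By this call, 13765 of 21938 protein-coding genes were occupied (62.75%, exact 95% interval 62.10 to 63.39), 7518 had no start-site peak in either replicate, 369 had one in replicate 1 only and 286 in replicate 2 only.

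The 5 strongest start-site peaks of the pooled list belonged to Sp3, Srsf6, Mex3b, Dbn1 and Fkrp. The transcription factor Sp3 (chromosome 2, 72978386 to 72981471) had an enrichment of 31.95 in replicate 1, 30.47 in replicate 2 and 35.17 in the pooled list. The splicing factor Srsf6 (chromosome 2, 162930476 to 162933089) followed with a pooled enrichment of 34.04, and the RNA-binding protein gene Mex3b (chromosome 7, 82867267 to 82870811) with 30.77. Dbn1, which encodes the actin-binding drebrin of neurons, reached 29.80 and Fkrp, a glycosyltransferase gene, 29.66. The median over all protein-coding genes was 7.53, and 11.95 among occupied genes. The 5 genes with the widest domains all lay in Hox clusters. A single domain with 52108 covered bases over a span of 56126 ran across Hoxb3, Hoxb4, Hoxb5 and Hoxb6, and one of 24806 covered bases joined Hoxa1, Hoxa2, Hoxa3 and the neighbouring coding gene 5730596B20Rik. The median domain of occupied genes covered 1955 bases.

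Genes of neurons and of their progenitors were occupied throughout. All 18 general neuron genes had a start-site peak in both replicates, led by the microtubule regulator Stmn3 with a pooled enrichment of 21.85 and the adhesion molecule gene Ncam1 with 21.78. All 16 neural progenitor genes were occupied, and Msi1 (20.89), an RNA-binding regulator of progenitors, and Id4 (19.90), which holds back differentiation, were the strongest. The 14 cell cycle genes were occupied as well, with Birc5 at 14.88 and Plk1 at 10.69. Against 62.71% or 62.72% of other genes, these shares gave adjusted p-values of 0.00108 for general neuron genes, 0.00278 for progenitor genes and 0.00406 for cell cycle genes (Fisher's exact test, two-sided, adjusted over the 28 lists alone). Also occupied in full were 20 housekeeping genes (adjusted p 4.89e-04), 24 genes of histone acetylation (adjusted p 1.30e-04) and 14 immediate early genes (adjusted p 0.00406). The strongest housekeeping genes were Eef1a1 (28.22), a translation factor gene, and Actb (28.19). Ep300 (29.51) and Hdac2 (21.70), an acetyltransferase and a deacetylase of histones, led the acetylation genes, while Dusp1 (18.26) and Btg2 (14.97) led the immediate early genes. In total, 8 of the 28 lists lay above other genes, 8 below and 12 passed in neither direction. Against genes of the same promoter CpG content, the calls of the cell cycle list (adjusted p 0.692) and the immediate early list (adjusted p 0.0833) ended, and among the upper 50% of peaks by enrichment so did that of the cell cycle list (adjusted p 0.224). The CpG-matched differences of progenitor, housekeeping and histone acetylation genes were 15.8, 13.5 and 19.6 points (adjusted p 0.0422, 0.0479 and 5.92e-04), down from 37.3 in each.

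**Figure D1:**
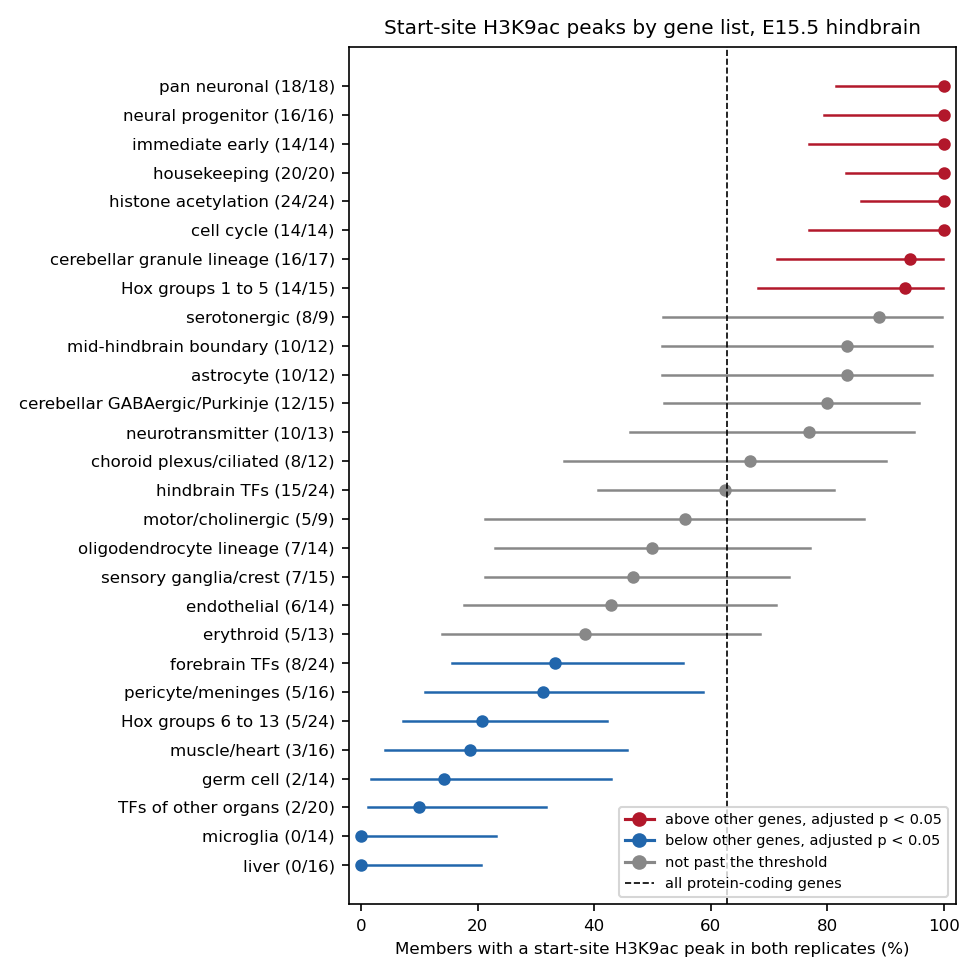
Percent of the members of each of the 28 fixed gene lists with a start-site H3K9ac peak in both replicates, with exact 95% binomial intervals; the dashed line is the 62.75% of all protein-coding genes. General neuron, progenitor, cell cycle, housekeeping, histone acetylation and immediate early genes sit at 100%, microglia and liver genes at 0%.

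Genes of the cerebellar lineages were largely occupied. Granule cell precursors arise from the rhombic lip and make up most cerebellar neurons, and 16 of the 17 genes of that lineage were occupied (94.12%, adjusted p 0.0103). Meis1 and Meis2, homeodomain factors of that lineage, had pooled enrichments of 21.30 and 16.21 and domains with 15511 and 22693 covered bases. These were the strongest of the list, whose median enrichment was 6.53, against 7.53 over all protein-coding genes. The weakest occupied members were Atoh1 (3.32), Barhl2 (3.44) and Barhl1 (3.74), named after their values were seen. Eomes, a gene of unipolar brush cells and of forebrain progenitors, was the unoccupied gene, with no peak in either replicate and a pooled enrichment of 2.48. Among genes of Purkinje cells and cerebellar GABAergic neurons, 12 of 15 were occupied (80.0%, adjusted p 0.270). Dab1, which relays reelin signals in migrating neurons, reached 15.90 and Rora, a nuclear receptor needed by Purkinje cells, 15.34. The late Purkinje gene Pcp2 had no peak, Skor2 had one in replicate 1 only and Ptf1a one in replicate 2 only. The call of the granule lineage list ended against genes of the same promoter CpG content (adjusted p 1.0) and among the upper 50% of peaks by enrichment (adjusted p 0.496), and the Purkinje list turned from 17.3 to -4.9 points against genes of the same promoter CpG content.

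Genes that define hindbrain neuron classes passed in neither direction as lists. Of 24 transcription factors of hindbrain progenitor and neuron domains, 15 were occupied (62.5%, adjusted p 1.0), with Mafb at 8.06 and Lbx1 at 7.93 in the pooled list. Dbx1 and Dbx2, factors of dividing interneuron progenitors, had no peak in either replicate. Against genes of the same promoter CpG content this list fell by 26.3 percentage points (adjusted p 4.90e-04), whereas by the pooled list alone it lay 26.2 points above other genes (adjusted p 0.0103). Serotonergic neurons lie along the hindbrain midline, and 8 of their 9 genes were occupied (adjusted p 0.247 by Fisher's exact test). Gch1, an enzyme gene for a cofactor of serotonin synthesis, was the strongest at 7.92, followed by the serotonin transporter gene Slc6a4 at 5.66, and Tph2 had no peak. The serotonergic list lay 26.2 points above other genes, but turned to -6.13 with a −log10 q of at least 2, to -5.48 with an enrichment of at least 3 and to -25.2 in the upper 50% of peaks. Of 9 motor neuron and cholinergic genes, 5 were occupied (adjusted p 0.791 by Fisher's exact test), with the choline transporter gene Slc5a7 (6.48) and the neurofilament gene Prph (3.90) as the strongest. Of the other 4, Mnx1 and Tbx20 had no peak, Lhx4 had one in replicate 1 only and Isl1 one in replicate 2 only. The motor list turned from -7.2 points to 12.3 in the pooled list, and in the upper 50% of peaks it passed below other genes (-47.4 points), as did hindbrain factors (-37.7).

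Neurotransmitter and boundary genes passed in neither direction as lists. Of 13 neurotransmitter genes, 10 were occupied (76.92%, adjusted p 0.457). The GABA transporter gene Slc6a1 had a pooled enrichment of 15.43 and the glycine transporter gene Slc6a9 one of 13.06. The 3 without a peak in either replicate were Slc17a8, Th and Dbh, of which the latter pair are enzyme genes of noradrenaline synthesis. The transporter genes of noradrenaline (Slc6a2, 3.90) and dopamine (Slc6a3, 5.39), named after their values were seen, were occupied. Of 12 genes of the midbrain-hindbrain boundary, the signalling centre that patterns the cerebellum, 10 were occupied (83.33%, adjusted p 0.294). Gbx2 (8.22) and En1 (6.09) were the strongest, and the signal genes Fgf17 and Wnt1 had no peak. The boundary list turned from 20.6 points to -8.52 in the upper 50% of peaks and to -8.87 with 5′ ends only.

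Hox genes set positional identity along the hindbrain and spinal cord, and only the anterior paralog groups reach far into the hindbrain. Of the 15 Hox genes of groups 1 to 5, 14 were occupied, against 5 of the 24 genes of groups 6 to 13. The shares were 93.33% (68.05 to 99.83) and 20.83% (7.13 to 42.15), with an odds ratio of 53.2 (Fisher's exact test, p 1e-05, adjusted over 4 comparisons 1.34e-05). The test counts these genes as independent, although neighbours in a cluster can share a peak or a domain. Some annotated starts belong to long transcripts that begin among other Hox genes, as at Hoxa3 and Hoxc5, and with only the 5′ end of each gene as its start the split was 11 of 15 against 4 of 24, an odds ratio of 13.8 (p 6.67e-04). The strongest start-site peaks were at Hoxb2 (12.30), Hoxa1 (10.10) and Hoxa2 (10.05), and those of Hoxb3 and Hoxb4 were one peak of 9.40. Hoxb1 was the exception in groups 1 to 5, with a peak of 2.93 in replicate 1 only. In groups 6 to 13 the occupied genes were those next to the anterior groups in the Hoxa and Hoxb clusters, namely Hoxa6 (3.25), Hoxa7 (6.45), Hoxb6 (5.69), Hoxb7 (3.70) and Hoxb8 (4.58). In the Hoxd cluster the neighbour of the anterior groups, Hoxd8, had no start-site peak in either replicate. Hoxb9 and Hoxc6 had a start-site peak in replicate 2 only and Hoxd12 in replicate 1 only. No gene of groups 10, 11 or 13, among them Hoxa10 and Hoxa11, had one in either replicate.

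The Hox clusters differed in how much of their length was covered. Each cluster was measured from its first to its last Hox gene. Pooled peaks covered 38.0% of the Hoxa cluster, 37.1% of Hoxb, 22.1% of Hoxd and 9.8% of Hoxc. The order of the first pair did not hold, since Hoxb lay above Hoxa in replicate 1 (32.9% against 31.7%) and in the replicated list (35.1% against 34.0%), and Hoxc was at 5.7% in replicate 2. The Hoxb span begins at the outlying Hoxb13 (96194316), and its first pooled peak lay at 96272119. This empty stretch lowers the percent of Hoxb, so the clusters are not compared over like spans. They also hold different paralog groups, and the most anterior gene of Hoxc was Hoxc4. In the Hoxd cluster a domain of 14252 covered bases (74725129 to 74742167) lay at annotated starts of Hoxd4 and Hoxd3. The strongest start-site peak of Hoxd3 (74745630 to 74750603) lay outside this domain. In Hoxc only Hoxc4 (7.34) and Hoxc5 (6.82) were occupied. Against all other protein-coding genes, groups 1 to 5 lay 30.6 points higher (adjusted p 0.0263) and groups 6 to 13 fell by 42.0 points (adjusted p 2.68e-04), or by 69.3 against genes of the same promoter CpG content. The higher call of groups 1 to 5 ended against genes of the same promoter CpG content (adjusted p 0.168), with only the 5′ end of each gene as its start (adjusted p 0.386), and with stricter peaks by −log10 q (adjusted p 0.0946), by enrichment of at least 3 (adjusted p 0.0844) and in the upper 50% by enrichment (adjusted p 0.164). With these 3 kinds of stricter peaks 86.67%, 86.67% and 80.0% of the 15 genes were occupied, against 61.68%, 61.03% and 58.51% of all protein-coding genes. With 5′ ends only the shares were 73.33% and 58.87%, and against genes of the same promoter CpG content the difference was 13.6 points.

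**Figure D2:**
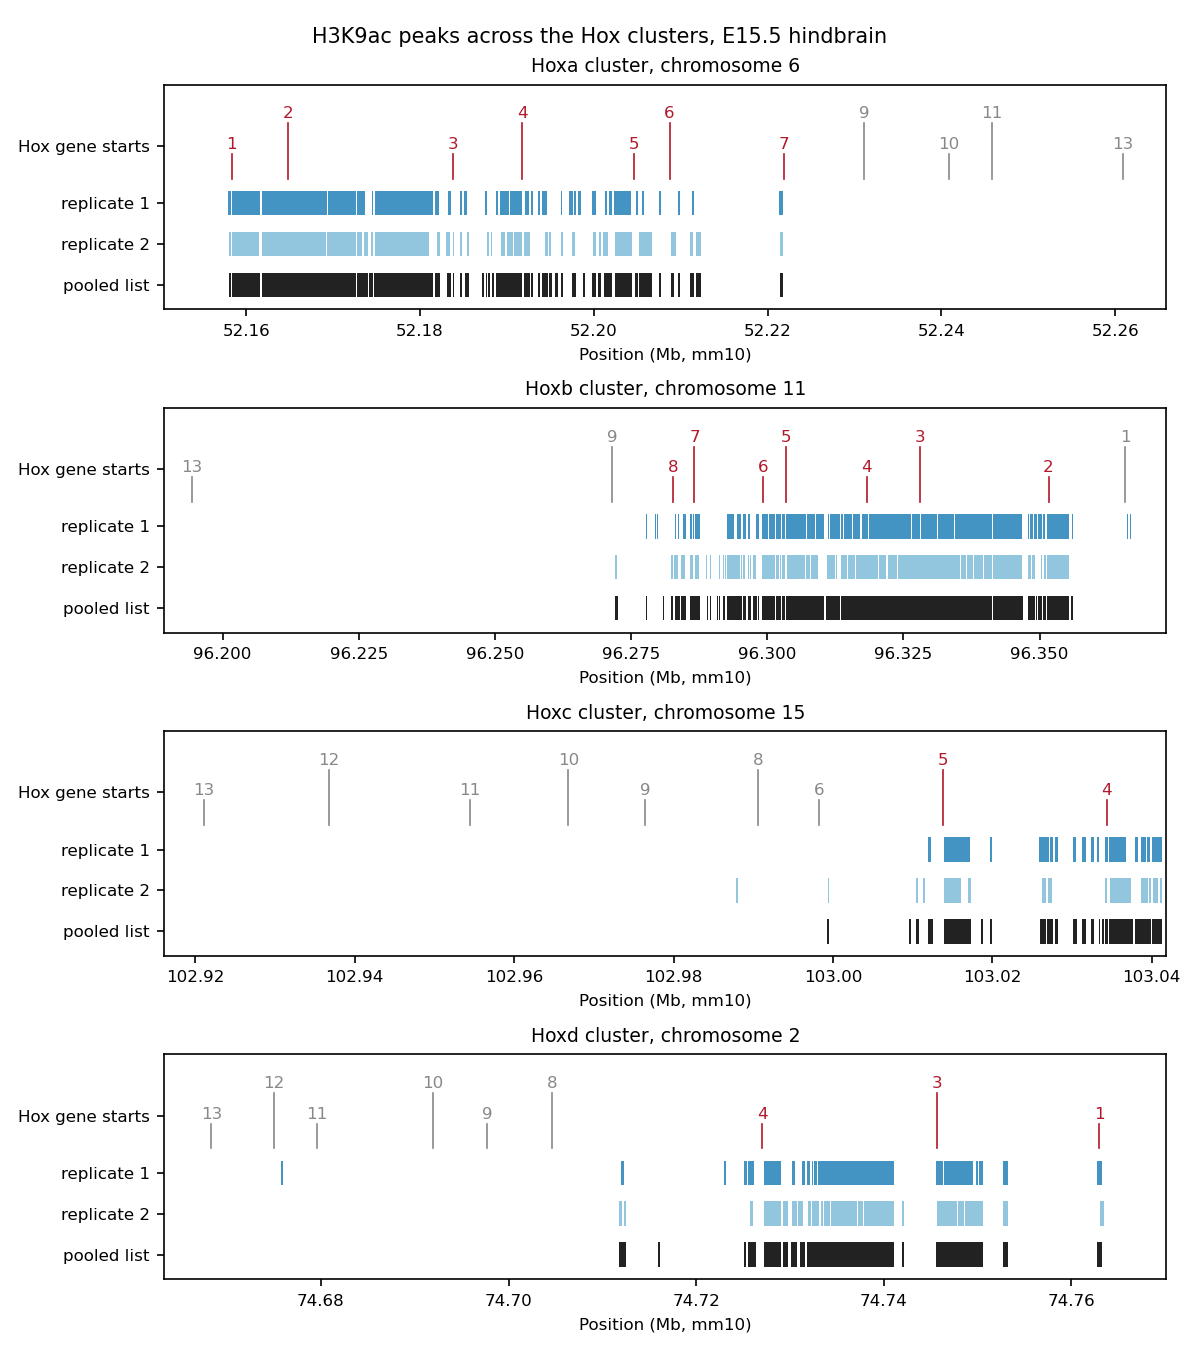
H3K9ac peaks across the 4 Hox clusters in both replicates and the pooled list, by mm10 position in Mb; ticks mark the paralog number of each gene, in red where both replicates had a start-site peak and in grey otherwise, placed at the annotated start nearest the strongest start-site peak for red genes and at the 5′ end for grey ones. Most peaks lie over groups 1 to 5, and few lie beyond Hoxa7, Hoxb8, Hoxc5 and Hoxd4.

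Forebrain transcription factors were mostly unoccupied. Of 24 such genes, 8 were occupied (33.33%, adjusted p 0.0103), with Bcl11b (14.82) and Satb2 (4.86), a pair of cortical projection neuron regulators, as the strongest. Arx and Dlx1, regulators of forebrain interneurons, had no peak in either replicate. After the shared gene Isl1 was left out, 15 of 23 hindbrain factors and 8 of 23 forebrain factors were occupied, a difference of 30.4 percentage points that did not pass (Fisher's exact test, p 0.0758). In the pooled list the difference was 39.13 points (p 0.00736), and in replicate 2 alone and replicate 1 alone it was 34.78 (p 0.0331) and 39.13 points (p 0.0169). It shrank to 26.1 points with 5′ ends only (p 0.12), to 17.4 with 500 bases around starts (p 0.373) and to 8.7 in the upper 50% of peaks (p 0.699). The lower call of forebrain factors ended in the pooled list (adjusted p 0.378) and in replicate 2 alone (adjusted p 0.151), and against genes of the same promoter CpG content the list lay at -51.4 points, from -29.4.

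The lists of cells that enter the hindbrain from outside the neural tube held many unoccupied genes. None of the 14 microglia and macrophage genes had a start-site peak in either replicate (upper limit 23.16%, adjusted p 1.38e-05), including Aif1 and the complement gene C1qa. The difference shrank from -62.8 to -27.4 points (adjusted p 0.00256) against genes of the same promoter CpG content. Of 13 red blood cell genes, 5 were occupied (38.46%, adjusted p 0.142), namely the transcription factor genes Nfe2 (6.18), Klf1 (5.55) and Tal1 (4.27), and Gypa (4.82) and Epor (3.67). Alas2 and Epb42 had none. This list turned from -24.3 to 10.4 points against genes of the same promoter CpG content. Of 14 endothelial genes, 6 were occupied (42.86%, adjusted p 0.247), with the junction gene Ocln at 8.41 and the growth factor receptor gene Kdr at 6.30, while Emcn and Pecam1 had no peak. This list passed below other genes with an enrichment of at least 3 (adjusted p 0.0422) and in the upper 50% of peaks (adjusted p 0.043). Of 16 pericyte and meningeal genes, 5 were occupied (31.25%, adjusted p 0.0291), namely Kcnj8 (5.45), Zic3 (4.27), Foxc1 (4.09), Twist1 (3.93) and Tbx18 (3.87). Aldh1a2 and Col3a1 had none. The lower call of this list ended in each replicate alone (adjusted p 0.676 in replicate 2 and 0.0601 in replicate 1), in the replicated list (adjusted p 0.191) and with 2000 bases around starts (adjusted p 0.0654), and in the pooled list it lay 3.28 points above other genes (adjusted p 1.0). Of the 16 genes, 6 had a peak in replicate 1 and 9 in replicate 2, against 64.43% and 64.05% of all protein-coding genes.

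Glial and choroid plexus genes passed in neither direction as lists. Of 14 oligodendrocyte genes, 7 were occupied (adjusted p 0.457). The myelin gene Mbp reached 14.33 and the precursor receptor gene Pdgfra 7.47, while Cspg4 and Gpr17 had no peak in either replicate. The Mbp peak lay at the gene's 5′ end (chromosome 18, 82474769 to 82476485), and which of its transcripts start there was not examined. Of 12 astrocyte genes, 10 were occupied (83.33%, adjusted p 0.294), led by Nfib (13.73), a regulator of gliogenesis, and by the glutamate transporter gene Slc1a2 (10.52). S100b had no peak, and Gfap had one in replicate 1 only. Against genes of the same promoter CpG content the astrocyte list lay 31.6 points higher and passed (adjusted p 0.0219), but in the upper 50% of peaks it turned to -16.9 points (adjusted p 0.297), from 20.6 in the main call. In those peaks the oligodendrocyte list passed below other genes (-37.1 points, adjusted p 0.0105). Of 12 choroid plexus and ciliated cell genes, 8 were occupied (66.67%, adjusted p 1.0), with the cilia genes Ccdc39 (8.43) and Foxj1 (7.69) as the strongest. The 4 without a peak were Ttr, Folr1, Kcne2 and Aqp1. This list turned from 3.9 points to -16.9 in the upper 50% of peaks and to -8.87 with 5′ ends only.

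Genes of liver, muscle, germ cells and other organs were rarely occupied. None of the 16 liver genes was occupied (upper limit 20.59%, adjusted p 3.82e-06); Afp and Ahsg had no peak, and Trf, named after its values were seen, had one in replicate 2 only. Of 16 muscle and heart genes, 3 were occupied (18.75%, adjusted p 0.0013), namely Mylpf (18.65), Ckm (5.35) and Myh7 (3.34), while Acta1 and Actc1 had no peak. The Mylpf peak also lay at a start of Tbc1d10b, and the Ckm peak at a start of Klc3. Of 14 germ cell genes, Gdf9 (11.31) and Dazl (5.38) were occupied (14.29%, adjusted p 0.00108) and Ddx4 and Mael were not. The Gdf9 peak also lay at a start of Uqcrq, a respiratory chain gene. These neighbours, like Ssrp1 below, were named after their values were seen. Such sharing with another coding gene was found for 3 of 25 occupied genes of the lists below other genes and for 15 of 135 of the lists above. Of 20 developmental transcription factors of other organs, Tbx6 (8.41) and Mesp1 (5.79) were occupied (adjusted p 1.41e-05), and the gut regulators Cdx1 and Cdx2 had no peak. Sensory ganglion and neural crest genes passed in neither direction, with 7 of 15 occupied (46.67%, adjusted p 0.346). The neurotrophin receptor gene Ntrk2 had 20.29 and P2rx3 had 16.09, in a peak that also lay at a start of the histone chaperone gene Ssrp1, while Isl2 and Prdm12 had no peak. The lower call of the muscle and heart list ended against genes of the same promoter CpG content (adjusted p 0.0659), and there the liver list lay at -26.0 points (adjusted p 0.0364), from -62.8. In the upper 50% of peaks sensory ganglion genes passed below (adjusted p 0.0257).

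Strength and breadth separated the lists in different ways. Housekeeping, histone acetylation and general neuron genes had both strong peaks and wide domains. Against genes of the same promoter CpG content they lay 16.9, 20.8 and 24.9 rank points higher in strength and 17.4, 16.3 and 34.5 in breadth. Each of these differences was smaller than against unmatched random lists. Progenitor, granule lineage, Hox 1 to 5 and immediate early genes had wide domains, but as lists they did not pass above random lists in strength. Single members, such as Msi1 (20.89) and Meis1 (21.30), still had strong peaks. By peak strength, 3 lists ranked above random lists and 10 below, and by breadth 8 ranked above and 8 below. Among genes with a peak 19 lists ranked below in strength and 10 in breadth, with 7 of the 10 and 4 of the 8 main lists among them, while microglia, liver and germ cell genes, with under 3 such genes, were not tested and Hox 6 to 13 turned to 6.8 rank points in breadth. Against genes of the same promoter CpG content 15 lists ranked below in strength and 9 in breadth, and the calls of red blood cell genes (adjusted p 0.483 and 0.587) and muscle and heart genes (0.0693 and 0.0604) ended. With 5′ ends only, the strength call of endothelial genes ended (adjusted p 0.0608). The mean strength rank, from 0 to 100, was 81.4 for general neuron genes, 81.2 for histone acetylation genes and 80.7 for housekeeping genes (adjusted p 4.67e-05 each by the permutation test, at the smallest raw p it can give). Hox groups 1 to 5 had a mean strength rank of 49.7 (adjusted p 0.970) and a mean breadth rank of 89.8 (adjusted p 4.00e-05), with a median of 14252 covered bases. Several of these genes share a domain, and with 1 gene kept per domain the remaining 9 had a median of 8433 covered bases and a mean breadth rank of 83.0 (adjusted p 4.76e-04). Progenitor genes had ranks of 59.7 for strength and 90.3 for breadth, granule lineage genes 53.1 and 83.8, and immediate early genes 57.1 and 82.5. Purkinje and cerebellar GABAergic genes were the other list above in breadth, with a mean rank of 73.9 (adjusted p 0.0014). They too did not pass above random lists in strength, with a mean strength rank of 48.7 (adjusted p 0.928), although Dab1 reached 15.90. Among genes with a peak, strength fell by 23.3 rank points for Hox 1 to 5 (adjusted p 0.00241), fell by 21.6 for granule lineage genes (adjusted p 0.0021) and fell by 15.6 for immediate early genes (adjusted p 0.0491), while progenitor genes were at -11.6 and did not pass (adjusted p 0.111).

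**Figure D3:**
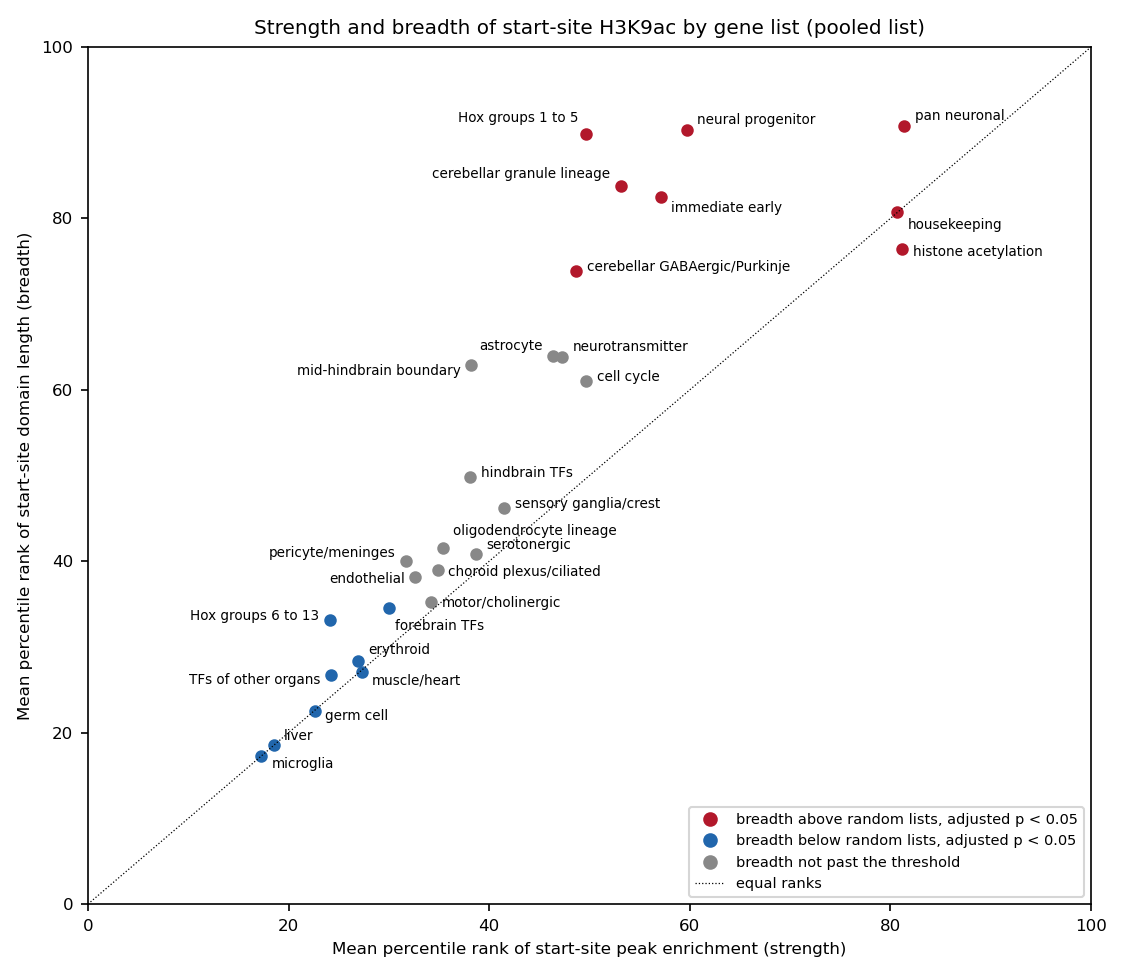
Mean percentile rank of start-site peak enrichment (horizontal) and of start-site domain length (vertical) of each gene list among protein-coding genes in the pooled list; red and blue mark lists whose breadth passed above and below random lists. Progenitor, granule lineage, Hox 1 to 5 and immediate early genes lie far above the line of equal ranks. Purkinje and cerebellar GABAergic genes and mid-hindbrain boundary genes lie about as far above it as immediate early genes.

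Promoters rich in CpG dinucleotides, which many housekeeping and developmental genes have, were nearly all occupied. Of 10083 CpG-rich promoters, 9729 were occupied (96.49%, 96.11 to 96.84), against 4036 of 11855 CpG-poor ones (34.04%, 33.19 to 34.91), an odds ratio of 53.2 (Fisher's exact test, p too small for double precision). CpG content was measured at the gene's 5′ end, while a peak at any annotated start counted. A gene with a CpG-poor 5′ end could therefore be occupied through another start, also where lists were matched on promoter CpG content. This comparison was not made with 5′ ends only. Among noncoding genes, those transcribed from bidirectional promoters were occupied in 173 of 190 cases (91.05%). Only 1 of the 190 lay over 2000 bases from a coding start, and it was not occupied, so their peaks cannot be told from those of coding starts. Antisense transcripts were occupied in 32.82% and lincRNA genes in 13.19%, and over 2000 bases from coding starts these shares were 6.43% and 7.64%. Processed pseudogenes were occupied in 107 of 9940 cases (1.08%), and whether near-identical copies elsewhere lowered this share was not tested. None of the 218 immunoglobulin variable genes (upper limit 1.68%) and none of the 144 T cell receptor variable genes (upper limit 2.53%) was occupied.

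Genes of the X chromosome were occupied less often than autosomal genes in these pools of both sexes. On the X, 446 of 948 protein-coding genes were occupied (47.05%, 43.83 to 50.28), against 13315 of 20807 on autosomes (63.99%), and the share fell by 16.9 percentage points (Fisher's exact test, p 3.79e-25, adjusted over 4 comparisons 7.59e-25). Among CpG-rich promoters the shares were 90.98% of 255 and 96.65% of 9822, so that the share on the X fell by 5.67 points (p 2.88e-05). Apart from the Y chromosome, pooled peaks were sparsest on the X, with 6.1 per Mb, and densest on chromosome 11, with 35.6 per Mb. On the Y chromosome 4 of 183 genes were occupied, namely Ddx3y (4.43), Eif2s3y (3.82), Kdm5d (3.21) and Uty (6.57), which were named after their values were seen. Among autosomal CpG-rich promoters, 41.09% of 129 with a near-identical copy elsewhere were occupied, against 97.39% of 9693 without one. Whether such copies lowered the share on the Y was not tested.

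Peaks far from annotated starts mark candidate enhancers by position only. Of 24872 pooled peaks found in both replicates, 3297 lay over 5000 bases from any annotated start (13.26%, 12.84 to 13.68), with a median enrichment of 3.83 against 9.40 at starts. The count was 6203 with replicate 2 alone, 6982 with replicate 1 alone and 1092 among the upper 50% of peaks by enrichment. The share depends on this filter, since 23.1% of distal pooled peaks were found in both replicates, against 59.7% of the others. In the full lists 25.89% (replicate 1), 22.35% (replicate 2) and 28.32% (pooled) of peaks were distal. The strongest distal peak found in both replicates lay between genes on chromosome 12 (8640747 to 8641723), with an enrichment of 14.7 in replicate 1, 22.1 in replicate 2 and 23.85 in the pooled list. The nearest coding start, 33209 bases away, was that of the RNA-binding protein gene Pum2. The next were on chromosome 15 (96709934 to 96710694), at 19.87 and 10410 bases from the amino acid transporter gene Slc38a2, and on chromosome 8 (69716100 to 69716964), at 18.15 and 5990 bases from Zfp869. The other 2 of the strongest 5 lay on chromosome 1 (171038095 to 171038597), at 17.28 and 19366 bases from Fcgr4, and on chromosome 8 (83874545 to 83877044), at 17.12 and 24879 bases from the synaptic adhesion receptor gene Adgrl1. The peak near Zfp869 lay within 1000 bases of a RefSeq gene start, and that near Fcgr4 within 1000 bases of a tRNA gene.

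Most peaks of each replicate had a counterpart in the other, and the strongest peaks nearly always did. In replicate 1, 28498 peaks were shared with replicate 2 (60.69%, 60.25 to 61.13) and 18458 were not. In replicate 2, 29147 were shared (68.78%, 68.34 to 69.22) and 13228 were not. After shuffling, the shares were 2.13% and 2.37%. Ordered by enrichment into 4 equal parts from weakest to strongest, the peaks of replicate 1 were shared in 23.3%, 37.0%, 82.4% and 100% of cases, and those of replicate 2 in 36.0%, 47.8%, 91.3% and 100%. Across the 32751 overlapping pairs, which are not independent, enrichment had a Spearman correlation of 0.609 and a Pearson correlation of log2 values of 0.617. The strongest peaks of replicate 1 without a counterpart were at an exon of Gm42743 on chromosome 3 (96277683 to 96278121, enrichment 7.72), in an untranslated region of Zic1 on chromosome 9 (91359958 to 91360559, 7.19) and 308 bases from the start of Zfp180 on chromosome 7 (24081186 to 24081754, 7.10). In replicate 2 they all had an enrichment of 6.86 and lay on chromosome 11 (67819739 to 67820053, 21606 bases from Dhrs7c), on chromosome 4 (155408782 to 155409151, in an exon of 5830444B04Rik) and on chromosome 5 (74092615 to 74092912, in an exon of Gm43416).

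**Figure D4:**
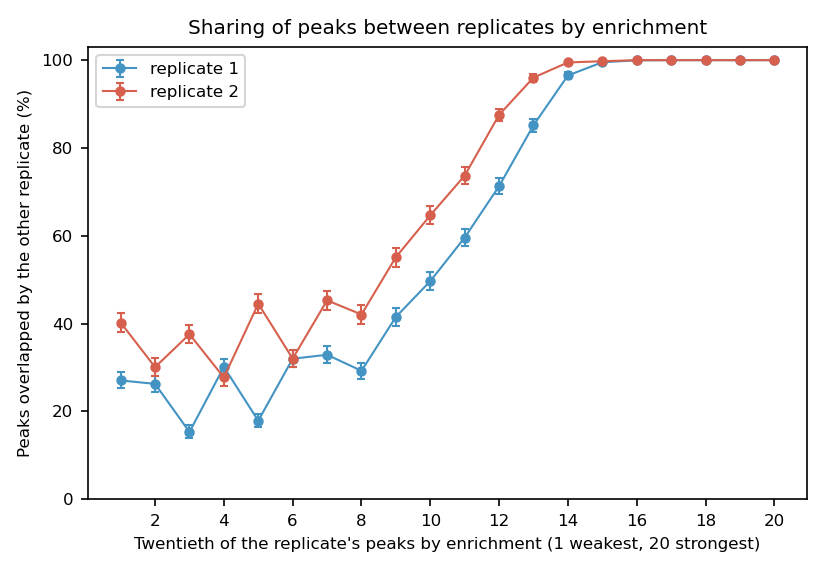
Percent of the peaks of each replicate that overlap a peak of the other, by 20 equal classes of enrichment from weakest to strongest, with exact 95% binomial intervals. In both replicates nearly all peaks of the stronger classes were shared.

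Gene starts held most of the shared peaks and a smaller share of the others. In replicate 1, 52.87% of peaks lay within 1000 bases of an annotated start (52.42 to 53.32), against 8.22% after shuffling, and in replicate 2 57.43% did (56.96 to 57.90), against 8.30%. Peaks at starts had a median enrichment of 6.66 and a median width of 760 bases in replicate 1, against 3.11 and 241 bases elsewhere. In replicate 2 these values were 6.40 and 749.5 bases, against 3.05 and 249 bases. By their summits, 28.6% of the peaks of replicate 1 and 25.89% of those of replicate 2 lay in introns, and 15.93% and 14.19% lay between genes. Of the shared peaks of replicate 1, 73.5% were at starts, against 21% of the others (odds ratio 10.4), and in replicate 2 73.4% against 22.2% (odds ratio 9.70). Fisher's exact test gave p-values too small for double precision in both. It counts peaks as independent and does not separate their place from their width and enrichment, which were higher at starts.

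All 27563 replicated peaks were found unchanged in the pooled list, and all 22128 pooled peaks with at least 50% of their length covered by each replicate's peaks were among them. Of the replicated peaks, 89.53% were touched by peaks of both replicates, while 2885 (10.5%) were not and 158 were touched by neither. Of all pooled peaks, 49.35% were touched by both. Replicated peaks lay at starts in 70.78% of cases and pooled peaks in 48.89%.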

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

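No test in this part was chosen after the result was seen. The comparisons of genes and starts left out unplaced scaffolds, which entered only the overlaps between lists, yet 12 peaks of the pooled list lay on 5 scaffolds. Of these peaks, 10 were found in both replicates and 7 lay within 1000 bases of an annotated gene start. The strongest was at the start of Vamp7 on a scaffold assigned to the X chromosome, with an enrichment of 9.17 in the pooled list, and Tmlhe on the same scaffold had 3.36. Vamp7 encodes a membrane fusion protein and Tmlhe an enzyme of carnitine synthesis. The names were chosen after the values were seen, and no biological explanation was tested.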

How the results depend on the processing

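The tests of stricter peaks of 1 replicate against the full list of the other were chosen only after the result was seen; so were the X comparison without receptor genes (-21.3 points, the same call) and starts extended by RefSeq (2588 distal peaks), and breadth with 1 gene kept per domain, which kept the call of every list. Of 169 values of the main results under alternatives, 119 kept their call or stayed within their interval, 45 moved and 5 crossed to the called side. Of 694 values of single gene lists, 591 kept direction and call, 43 crossed to the called side, 22 lost their call and 38 changed direction. Of the 16 lists called by occupancy, 158 of 176 values kept the call, 17 lost it and 1 turned. The cause was not tested, except where the construction of an alternative gives it. No paired analysis was possible because the series holds 1 group.

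With a −log10 q of at least 2, the start-site shares were 63.16% and 66.14% (replicates 1 and 2), the overlaps 70.28% and 76.06%, or 74.54% and 79.42% against the full other list, the hindbrain over forebrain difference 34.78 points (p 0.0287), and serotonergic occupancy -6.13 points. With an enrichment of at least 3 they were 64.28% and 68.16%, overlaps 69.19% and 76.57%, distal peaks 1994, the hindbrain over forebrain difference 30.4 (p 0.0574), serotonergic -5.48 and choroid plexus -2.70. In the upper 50% of each list they were 78.29% and 82.63%, overlaps 79.75% and 88.84%, or 91.19% and 95.61% against the full other list, distal peaks 1092, the hindbrain over forebrain difference 8.7 (p 0.699), and 5 lists lay above and 14 below other genes, with serotonergic -25.2, mid-hindbrain boundary -8.52, astrocyte -16.9 and choroid plexus -16.9. Fewer genes were occupied under these stricter peaks by construction.

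With 500 bases around starts the shares were 46.1% and 50.74%, the hindbrain over forebrain difference 17.4 points (p 0.373), choroid plexus occupancy -3.73 and cell cycle strength 0.0153. With 2000 bases they were 62.51% and 66.84%, the hindbrain over forebrain difference 34.78 (p 0.0377), and hindbrain factor occupancy 3.04. With 5′ ends only, the hindbrain over forebrain difference was 26.1 (p 0.12), mid-hindbrain boundary and choroid plexus occupancy were both -8.87 and cell cycle strength 2.75. With the replicated list the hindbrain over forebrain difference was 30.4 (p 0.0746). With the pooled list the hindbrain over forebrain difference was 39.13 (p 0.00736), hindbrain factor occupancy 26.2, motor 12.3 and pericyte 3.28. Against the same CpG content 5 lists lay above other genes; Purkinje occupancy was -4.89, choroid plexus -2.23 and red blood cell 10.4, strength was -3.10 for progenitor, -11 for granule lineage, 2.46 for neurotransmitter, 4.01 for astrocyte and -3.90 for immediate early genes, and cell cycle breadth was -5.75.

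Among genes with a peak, 19 lists lay below in strength; strength was -11.6 for progenitor, -21.6 for granule lineage and -15.6 for immediate early genes, and breadth -9.51 for cell cycle and 6.76 for Hox 6 to 13. With a merging gap of 3000 bases, hindbrain factor breadth was 5.56.

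With 50% of a peak covered, the overlaps were 54.45% and 62.67%, the Spearman correlation 0.762, and pooled and replicated peaks in both replicates 43.89% and 80.28%; with 50% of both peaks they were 44.72%, 49.56%, 0.858, 38.83% and 71.04%, and distal peaks 2114. With −log10 p the correlation was 0.651. With a distal limit of 1000 bases there were 6214 distal peaks.

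Without either replicate in turn, the pooled peaks found ranged from 63.63% to 67.28%, the replicated peaks from 93.83% to 95.13%, distal peaks from 6203 to 6982, the hindbrain over forebrain difference from 34.78 to 39.13, hindbrain factor occupancy from 6.41 to 15.1, motor occupancy from 2.24 to 2.62 and Hox 1 to 5 strength from 1.49 to 2.36. Cell cycle strength ranged from -1.47 to 0.625. Read depth is unknown, so what depth limits was not measured.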

Other observations

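The tests of weak peaks, promoter CpG content, the merging step, 1 gene per domain and gene families were chosen only after the result was seen. Families of ribosomal, respiratory and proteasome genes were nearly all occupied, and chemosensory receptor families almost never. Of 36 families taken by symbol, 10 lay above other genes, 11 below, and 15 passed in neither direction (Fisher's exact test, adjusted over the 36). All 78 mitochondrial ribosomal protein genes and all 34 tRNA synthetase genes were occupied, as were 76 of 79 cytosolic ribosomal protein genes, where Rpl10l, Rpl39l and Rpl3l were not. Complex I had 36 of 37 subunits occupied, without Ndufa4l2, and the proteasome 38 of 40, without Psma8 and Psmb11. Of 1135 olfactory receptor genes only Olfr94 was occupied, and of 331 vomeronasal receptor genes only Vmn1r4. The families and these names were chosen after the values were seen. Whether near-identical promoter copies lowered the share of any family was not tested.

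Some families of neurons and of their wiring lay above other genes. No family was compared with genes of the same promoter CpG content, and that matching ended several higher calls of the fixed lists. All 22 ephrin and ephrin receptor genes (adjusted p 1.26e-04), 18 of 20 semaphorin genes (adjusted p 0.0182) and 24 of 25 glutamate receptor genes (adjusted p 4.58e-04) had a start-site peak in both replicates. Grin2c, an NMDA receptor subunit gene of mature cerebellum, was the exception among glutamate receptors. Of 40 voltage-gated potassium channel genes, 34 were occupied (adjusted p 0.00543), as were 339 of 394 zinc finger protein genes (adjusted p 4.51e-24). Clustered protocadherins, whose many alternative promoters give neurons their surface identity, were occupied in only 6 of 57 genes (10.53%, adjusted p 1.33e-15). T-box factors were occupied in 5 of 16 genes (adjusted p 0.0285). Other neuronal families passed in neither direction, namely synaptotagmins (15 of 17, adjusted p 0.0675), the netrin and slit pathway (15 of 18, 0.137), voltage-gated calcium channels (12 of 14, 0.146), acetylcholine receptors (7 of 16, 0.182), glycine receptors (4 of 5, 0.739), GABA-A receptors (13 of 19, 0.836) and sodium channels (6 of 10, 1.0), by Fisher's exact test. Of 403 tRNA genes, 208 had a peak in both replicates (51.6%).

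Peaks found in 1 replicate only were mostly weak, which may be why they lacked a counterpart. At most 0.009% of the strongest of the 4 equal parts of each list was found in 1 replicate only, and 88.8% and 93.0% of the single-replicate peaks came from the lower 50% of their list by enrichment. A further candidate is that wide domains were broken up differently at their flanks. On average 27.87% of the single-replicate peaks lay within 1000 bases of a shared peak, against 2.99% and 2.97% after shuffling, so broken flanks stay open for part of them. No biological explanation was tested.

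The lower occupancy of the X chromosome was set against 3 explanations. Promoters with near-identical copies elsewhere were not the whole cause, since without them the difference among CpG-rich promoters was -4.36 percentage points (Fisher's exact test, p 3.51e-04); copies on unplaced scaffolds were not sought. Promoter CpG content was not the whole cause either, with a difference of -5.7 points among CpG-rich promoters. Over all genes the difference was -16.9 points, and CpG-rich promoters were rarer on the X (255 of 948 genes) than on autosomes (9822 of 20807). CpG content may therefore give part of the lower occupancy, and how much was not measured. Lower enrichment on the X as a whole may contribute, because the median enrichment of occupied CpG-rich promoters was 8.87 on the X and 13.08 on autosomes, a difference of -32.2% (permutation test, p 1e-05, the smallest it can give). These medians cover only promoters with a peak, and whether lower enrichment cost the X any calls was not tested. Other differences in gene content between the X and autosomes were not tested either. That males carry 1 X and females silence 1 is a possible biological source, which these pools of both sexes could not test.

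Progenitor, granule lineage, Hox 1 to 5 and immediate early genes had wide domains, but as lists they did not pass above random lists in peak strength. For this pattern 2 technical explanations were tested on these 4 lists. Purkinje and cerebellar GABAergic genes had the same pattern but were not part of these tests. Many transcript starts close together were not the whole cause, since against random lists matched on the number of nearby starts all 4 lists kept a permutation p of 1e-05, the smallest it can give. Weak peaks joined by the merging step were not the whole cause either, since without merging the adjusted p was 3.50e-05 for 3 of the 4 lists and 0.00112 for immediate early genes. Against genes of the same promoter CpG content the adjusted p of all 4 was 5.60e-05 or lower. The breadth differences there were 27.8 rank points for progenitor, 20.1 for granule lineage, 31.7 for Hox 1 to 5 and 22.0 for immediate early genes. Each was smaller than against unmatched random lists. With 1 gene kept per domain the adjusted p was 4.76e-04 for Hox 1 to 5. That developmental and inducible genes of this tissue carry wide acetylated domains stays a hypothesis, since no biological explanation was tested.

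No gathering of distal peaks was found around 4 neural lists named in advance, which does not show that there was none. Of the general neuron, progenitor, granule lineage and Hox 1 to 5 lists, 0 had more distal peaks within 100000 bases of their genes than random lists after adjustment. Progenitor genes had a mean of 1.06 per gene (raw p 0.016, adjusted p 0.0897), while general neuron genes had 0.33 (adjusted p 1.0), granule lineage genes 0.59 (adjusted p 0.587) and Hox 1 to 5 genes 0.53 (adjusted p 0.839). Among all 28 lists, 3 passed, with means per gene of 1.79 for immediate early genes (adjusted p 0.0174), 1.60 for Purkinje and cerebellar GABAergic genes (adjusted p 0.0207) and 1.08 for Hox 6 to 13 (adjusted p 0.0419), against 0.38 over all genes. The value of Hox 6 to 13 comes from 6 distinct peaks counted 26 times over neighbouring genes, which random lists of scattered genes do not allow for, so it is not read as a difference. Pax2, with 6 distal peaks, and Ier2, with 5, were among the richest genes of these lists and were named after their values were seen.

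Some of the strongest distal peaks may be starts that the main annotation lacks. Of the 100 strongest, 37.0% (27.56 to 47.24) lay within 1000 bases of a RefSeq gene start or tRNA gene, against 12.07% of the other distal peaks and 5.07% after shuffling. The interval lies below 50%, so missing starts stay open for part of these peaks. Near a tRNA gene lay 9 of the 100 strongest and 83 of the other 3197 (Fisher's exact test, p 0.00163).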
